A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

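RNA was measured in the fission yeast Schizosaccharomyces pombe on 8 one-colour (Cy3) Agilent gene expression arrays, 2 for each of 4 genotypes: wild type, a full deletion of set2, a C-terminal deletion of set2 and a deletion of the SRI domain of set2. Cells were grown in rich YES medium at 30 °C to exponential phase, and 200 ng of RNA were labelled per array. Per the file headers, each array was scanned and read with Agilent Feature Extraction 10.7.3.1, and the deposited signal per spot is a background-subtracted, detrended intensity that was not normalised between arrays. The value table deposited with the series is also an intensity, and its source is not stated. For 99.0% of probes it equalled, within a tolerance of 0.001, a constant per array times the median processed signal over the probe's spots, and 25 of its 6767 probes lacked a value on at least 1 array.

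Each array held 61657 spots other than controls and 1319 control spots. The 61657 spots carried 6711 probes. Outlier spots and control spots were left out, and the other spots of a probe were averaged. Of the 6711 probes, 104 whose names begin with ho-, a prefix that neither the files nor the labels explain, were kept out of the gene tests and tested on their own. The other 6607 gave 1 feature each, with 1 probe per gene, so the mean of a gene's probes and its brightest probe were the same value. Locus tags of 6424 of the 6711 probes (95.7%) matched the reference annotation. Distances from chromosome ends came from that annotation, and the coordinates given are those in the array files, which name an NCBI build of the genome. Of the features with both positions, 99.98% overlapped the reference gene of the same name. Probes for 223 features were marked as possibly multi-copy, because the probe name gives a repeat class (191 features) or because the probe shares a stretch of 20 bases with another probe (102 features). Genes so marked are named as uncertain.

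The log2 processed signal was centred on the 75th percentile of each array. A feature was tested when its probe was well above background, in over 0.5 of its spots, on both arrays of at least 1 genotype, which left 5340 features. All values given as log2 levels are relative to that percentile. One limma 3.58.1 model (R 4.3.3, with the data.table package at 1.17.8) was fitted to all 8 arrays with genotype as the only term, and eBayes moderated the variances. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over the 5340 features. The fit had 4 residual degrees of freedom and a prior worth 2.62. Errors of log2 changes are the moderated standard errors (SE), and errors of levels are standard deviations (SD) of 2 arrays.

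The replicate number is also the slide per the file headers, and every slide carried 1 array of each genotype. The deviations of replicate 1 from replicate 2 correlated between genotypes across genes, with r from 0.41 to 0.65, so the slides carried a shared effect. A fit with the slide as a block is therefore given beside those counts of called genes per comparison and per list in the results that it moved by over 1.5 times, and 3 residual degrees of freedom remained in it. The labels do not show whether the 2 arrays of a genotype came from separate cultures. If they did not, the p-values measure only the spread between these samples, which may be technical.

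Signal over background sets the limit of arrays. The number of probes well above background was 5034 and 5208 on the 2 wild type arrays and 5352 to 5457 on the mutant arrays, and no spot was saturated. Median processed signal ranged from 173 to 319 between arrays. The correlation between the 2 arrays of a genotype was 0.997 to 0.998 across genes. Where a gene was dim (not well above background) on both arrays of a genotype, its fold is given as "at least N-fold". That bound sets the mean of the brighter genotype against the mean, for the dimmer one, of the higher of 2 values per array: the lowest signal among probes well above background, and the probe's own signal. The number of arrays bounds the precision of every value.

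Tested on simulated data with the same spread, the model recovered 75.8%, 92.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale. These were 50 of 66, 62 of 67 and 67 of 67 genes. It made 15 false calls in 5140 unchanged genes, which is a larger share of the calls than of the 5140. The simulated noise was independent between arrays and held no slide effect.

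The comparisons, the model, 23 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The lists were genes within 50 kb and 50 to 100 kb of the ends of chromosomes I and II, Tf2 retrotransposons, noncoding RNA genes, mating-type cassettes, M-cell genes, P-cell genes, strain marker genes, heterochromatin machinery, partners of H3K36 methylation (the Clr6 and FACT complexes and histone chaperones), core meiosis genes, mug genes, meu genes, genes of nitrogen starvation and mating, core stress genes, chaperones, G1/S genes of the MBF regulon, histone genes, ribosomal protein genes, oxidative phosphorylation, iron and copper uptake, phosphate and thiamine genes, and flocculins. A further 7 lists were taken from the annotation on the array after the first values had been seen. They were antisense RNAs, intergenic RNAs, other noncoding RNAs, telomere repeat probes, wtf elements, dubious open reading frames and membrane transporters. Telomere repeat probes is the name given here to features whose systematic names begin with Tg. Their descriptions include protein families, a pseudogene and a truncated helicase. Because the 7 lists follow the annotation, they can overlap, and 4 telomere repeat probes described as noncoding RNA are also among the other noncoding RNAs. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over 84 tests of mutants against wild type or 56 between mutants. limma's fry, which asks whether the genes of a list moved on balance one way, was run beside it.

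Named genes were set2, then per mutant the 12 largest called changes each way with the same sign on both slides, up to 4 members of each list with the smallest p, and the 6 largest called each way between mutants. Because most of the largest increases were of genes dim in wild type, Tg08a, SPNCRNA.731 and SPBPB2B2.05, which were measured on all arrays, and ght3 in the comparisons with wild type were named after their values were seen. The same holds for gdt1, gal1, aes1, yhb1, pan5, SPBPB8B6.05c, SPAC977.12 and SPBPB21E7.09 near chromosome ends and for spd1, snz1, chl1, ino80 and rcd1 beside set2.

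The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, no filter on dim probes, only genes well above background on all 8 arrays, the slide as a block, only the arrays of the genotypes compared, a trended robust prior, the deposited value table, at least a 2-fold change, adjusted p under 0.01, an estimated correlation, subtelomere limits of 20 and 150 kb, and leaving out each array in turn. Leaving out multi-copy probes was added after the data were seen. Mean changes by distance from a chromosome end were taken in 25 kb steps to 200 kb. The overlap of the mutants was set beside 100 simulations of unchanged groups compared with a shared wild type.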

Results

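The series measured RNA levels in fission yeast cells that lacked all or part of Set2, the histone methyltransferase that places methyl groups on lysine 36 of histone H3. Each of 4 genotypes had 2 arrays: wild type, a full set2 deletion, a C-terminal deletion, and a deletion of the SRI domain, the part of Set2 that binds elongating RNA polymerase II. The series title concerns trimethylation of this lysine and gene silencing. Of 6711 probes, 5034 and 5208 were well above background on the 2 wild type arrays and 5352 to 5457 on the 6 mutant arrays. After the filter, 5340 features were tested, of which 4783 were open reading frames, 299 antisense RNAs and 141 intergenic RNAs. The rest were other noncoding RNAs, telomere repeat probes and 1 probe for the Tf2 retrotransposon.

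Signal for set2 itself (SPAC29B12.02c, chromosome I, 5408418 to 5410814) fell in all 3 mutants. Its log2 level in wild type was -3.02 ± 0.20 (SD, n = 2), relative to the 75th percentile of the array. It was dim on both arrays of every mutant, so that its level was at least 5.65-fold lower in the full deletion, 4.87-fold in the C-terminal deletion and 5.32-fold in the SRI deletion. The files do not say where in the gene the probe lies relative to the parts removed in the C-terminal and SRI deletions. Its place was not derived from the probe sequence. These values therefore do not show whether a shortened set2 RNA remained in those 2 mutants.

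The full deletion was compared with wild type to ask which RNAs change without Set2. The enolase gene eno102 (SPBPB21E7.01c, chromosome II, 58324 to 59646) rose 18.0-fold, by 4.17 ± 0.10 on the log2 scale (SE, 2 arrays against 2). The hexose transporter gene ght3 (SPAC1F8.01, chromosome I, from 82936) rose 8.10-fold, by 3.02 ± 0.23. The flocculin gene pfl9 (SPAC186.01, chromosome I, 5527692 to 5528672) rose by 3.89 ± 0.20, although 1 of the 2 wild type arrays did not measure it above background. Of 687 antisense RNAs on the array 299 passed the filter, and these had a median log2 change of 1.18. The filter favours rises, since a feature dim in wild type passes only through a mutant that measured it.

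All 14 tested protein-coding genes within 50 kb of these ends were called higher, as they were when adjusted over the list alone. Their median log2 change was 3.23, or 2.31 with genes dim in wild type at their bound. With normexp, which shrinks changes of dim genes, it was 1.19. This list passed limma's camera (adjusted p = 4.8e-11), but not with an estimated correlation (adjusted p = 0.177). Among the 45 genes 50 to 100 kb from an end, 35 were higher and 2 lower, or 38 and 2 adjusted over the list alone. Their median was 1.54, or 1.03 with bounds, 0.57 with normexp and 0.59 with only genes above background on all arrays (camera adjusted p = 2.1e-14, and 0.0471 with an estimated correlation). Genes there that were dim in wild type included the predicted phosphatase gene SPBPB2B2.06c, at least 48.1-fold higher but with a possibly multi-copy probe, and SPBPB2B2.08, at least 11.8-fold higher. The gene fah1 was at least 10.9-fold higher, the transporter gene SPBPB8B6.02c at least 7.83-fold and the hexose transporter gene ght7 at least 4.18-fold. Among genes measured on all arrays, cmt2 rose by 2.25 and SPBPB2B2.05 by 3.02, which is 8.12-fold.

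All 26 tested telomere repeat probes, the features with systematic names beginning with Tg, were called higher. Their median was 3.73, or 2.91 with bounds and 1.43 with normexp (camera adjusted p = 7.7e-20, and 0.0689 with an estimated correlation). Their descriptions include the DUF999 protein family (Tg13) and the 5Tm protein family (Tg14). A rise of RNA from the telomere repeat sequence itself was therefore not shown. All 26 are possibly multi-copy and have no position in the files. Tg08a, described as a truncated DNA helicase in a rearranged telomeric region, rose 25.5-fold, by 4.67 ± 0.14. Tg15 was at least 25.1-fold higher and Tg16 at least 14.5-fold. The telomere-linked helicase probe tlh1 rose by 5.04 ± 0.42, with signal above background on 1 of the 2 wild type arrays. Of the 335 features called at least 2-fold higher, 79 (23.6%) were telomere repeat probes or lay within 100 kb of an end of chromosome I or II.

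On chromosomes I and II the mean log2 change fell with distance from the end. It was 2.90 at 0 to 25 kb, where only 2 features were tested, 3.34 at 25 to 50 kb over 15 features, and 2.18 at 50 to 75 kb over 29. It was 1.43 at 75 to 100 kb, 0.48 at 100 to 125 kb, 0.31 at 125 to 150 kb and 0.12 beyond 200 kb, over 4059 features. The 2 outermost steps thus rest on few features. On chromosome III the means of the same steps lay between -0.15 and 0.23. Within 100 kb the mean exceeded that beyond 200 kb by 2.03, with 2.02 on slide 1 and 2.05 on slide 2. This difference was 1.56 with features dim in 1 genotype at their bound, 26 of the 73 within 100 kb, 0.87 with normexp and 1.15 with only genes above background on all arrays.

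**Figure D1:**
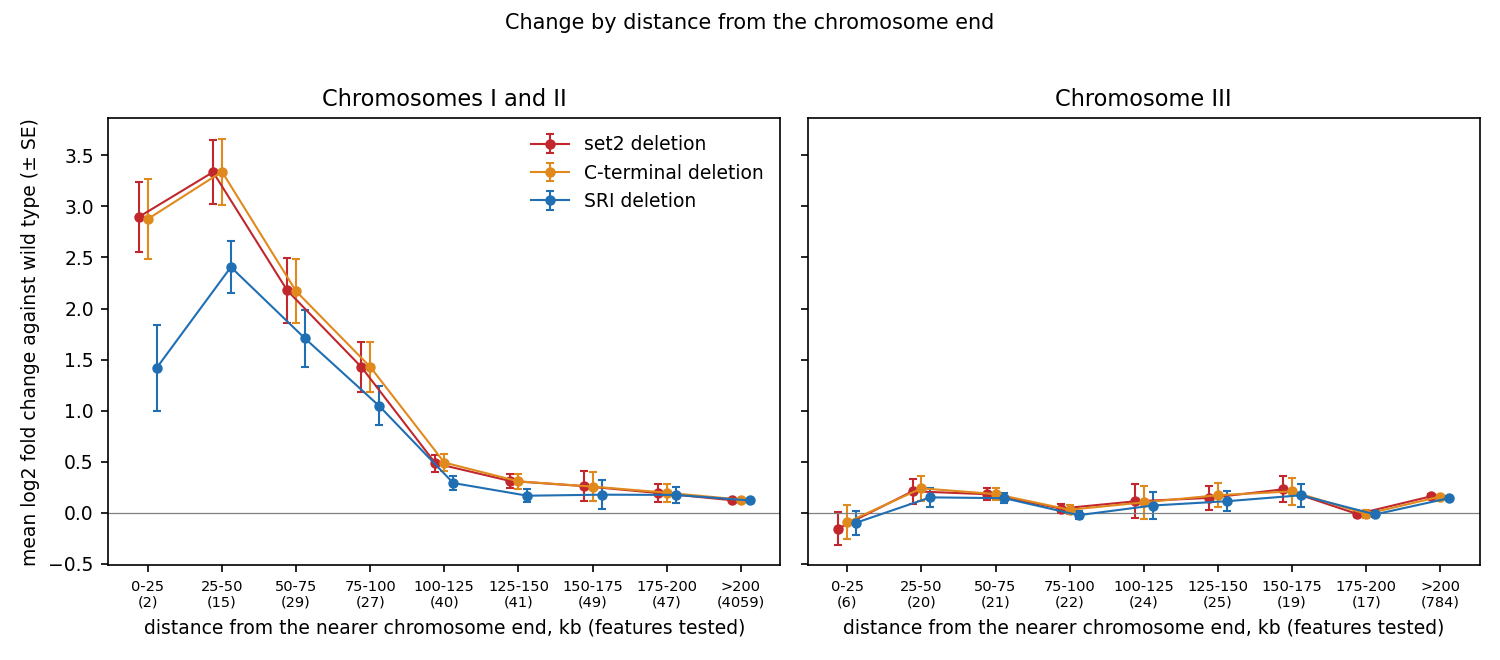
Mean log2 change against wild type (vertical axis, bars are standard errors over features) by distance from the nearest chromosome end in 25 kb steps (horizontal axis, kb), for chromosomes I and II and for chromosome III. In the set2 deletion the mean on chromosomes I and II was 3.34 at 25 to 50 kb and 0.48 at 100 to 125 kb.

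The noncoding RNAs that passed the filter, 532 of 1510 on the array, rose as a group. Part of this rise may come from the filter, which admits features dim in wild type only where a mutant measured them. Of 532 tested, 312 were higher and 29 lower, or 345 and 39 adjusted over the list alone and 367 and 49 with the slide as a block, with a median of 0.58, or 0.44 with bounds, 0.14 with quantile normalization, 0.12 with normexp and 0.28 with only those above background on all arrays (camera adjusted p = 1.5e-19, and 0.0163 with an estimated correlation). Of the 299 antisense RNAs, 231 were higher and 9 lower, or 255 and 15 with the block. Their median of 1.18 was 0.71 when those dim in wild type stood at their bound, 0.60 with quantile normalization, 0.23 with normexp and 0.46 with only those above background on all arrays (camera adjusted p = 1.5e-35, and 0.0115 with an estimated correlation). SPNCRNA.731 (chromosome I, from 1268172), measured on all arrays, rose 10.4-fold, by 3.38 ± 0.16. SPNCRNA.554 was at least 11.4-fold higher and SPNCRNA.1539 at least 9.49-fold. SPNCRNA.990 was at least 5.62-fold higher and SPNCRNA.569 at least 4.74-fold. In all, 195 features were dim in wild type and measured on both deletion arrays, 100 of them antisense, while 6 went the other way. Of 141 intergenic RNAs, 44 were higher and 11 lower, or 64 and 20 with the block, and the list did not pass camera (adjusted p = 0.0883). Of 91 other noncoding RNAs, 41 were higher and 9 lower, or 51 and 14 with the block, with a median of 0.32 that became -0.10 with quantile normalization and -0.14 without the filter (camera adjusted p = 0.00229, 0.0733 with an estimated correlation and 0.329 with normexp). By description this list holds 4 telomere repeat probes, and without them 37 of 87 were higher and 9 lower, or 47 and 14 with the block, with a median of 0.29 (camera adjusted p = 0.0146, and 0.184 with an estimated correlation). The lists of intergenic RNAs and of all noncoding RNAs hold 1 such probe each. The single Tf2 probe, which is multi-copy, rose by 0.51 ± 0.09 and was the only member of its list.

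Genes of meiosis and mating moved both ways. The meiotic genes rec10 (SPAC25G10.04c) and meu6 (SPBC428.07) rose 4.51-fold and 9.04-fold, by 2.17 ± 0.08 and 3.18 ± 0.05, and meu6 was above background on 1 of the 2 wild type arrays. The recombinase gene dmc1 rose by 1.27. The starvation genes isp4 and isp5 rose by 1.76 and 1.30, while ste11, which encodes the transcription factor that starts mating, fell by 0.80 and mei2 fell by 0.90. Of the 16 core meiosis genes 3 were higher and 3 lower, or 5 and 3 adjusted over the list alone and 7 and 4 with the block (camera adjusted p = 0.997). Of 17 genes of nitrogen starvation and mating, 6 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.253). Among 83 mug genes 30 were higher and 12 lower, or 35 and 13 adjusted over the list alone (camera adjusted p = 0.222), and mug137 was at least 8.32-fold higher. The 13 meu genes had 6 higher and 1 lower, also when adjusted over the list alone, or 6 and 2 with the block, with a median of 0.13 that became -0.03 with quantile normalization (camera adjusted p = 0.0475, 0.349 with an estimated correlation, 0.0677 with the block and 0.121 with normexp). Of 5 M-cell genes 3 were higher, also adjusted over the list alone: mam3 rose by 1.00, sxa2 by 0.65 and mam2, dim on both wild type arrays, by a fitted 0.66 that became -0.20 with quantile normalization and -0.03 with normexp (camera adjusted p = 0.0542, 0.0462 with the block and 0.439 with an estimated correlation). Of 3 P-cell genes, map4 alone was called, higher by 1.36, also adjusted over the list alone (camera adjusted p = 0.625). None of the 4 mating-type cassette genes on the array passed the filter.

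Of 9 flocculin genes at the cell surface 7 were higher, or 8 adjusted over the list alone, with a median of 1.16, or 0.64 with normexp (camera adjusted p = 0.00151, and 0.235 with an estimated correlation). The gene gsf2 rose by 1.49 and pfl7 by 1.33. Of 166 membrane transporter genes 45 were higher and 17 lower, or 72 and 27 with the block (camera adjusted p = 0.203). Of 11 genes of iron and copper uptake 2 were higher, also adjusted over the list alone, or 5 higher and 1 lower with the block (camera adjusted p = 0.433). The 2 called without the block were the siderophore synthetase gene sib1, which rose by 1.30, and str3, at least 2.44-fold higher. Of 10 genes of phosphate and thiamine uptake 5 were higher and 1 lower, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.163), and nmt1 was at least 2.34-fold higher. The invertase gene inv1 was at least 4.32-fold higher.

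Among changes of at least 2-fold 18 were decreases. The glutathione transferase gene gst2 (SPCC965.07c, chromosome III, 2295375 to 2296067) fell by 1.46 ± 0.14 on the log2 scale. In the pheromone pathway the adaptor gene ste4 fell by 1.22 ± 0.07 and the MAP kinase kinase gene byr1 by 1.19 ± 0.09. The reductase gene SPBC215.11c fell by 1.57 ± 0.10. The noncoding RNA SPNCRNA.1255, dim on both deletion arrays, was at least 2.29-fold lower, and SPCC330.19c at least 1.60-fold. Of 45 genes of oxidative phosphorylation 15 were lower and 1 higher, or 16 and 2 adjusted over the list alone and 24 and 4 with the block. Their median was -0.15 (camera adjusted p = 3.2e-07, and 0.0471 with an estimated correlation), with atp10 at -0.43 and cox7 at -0.48. The G1/S cyclin gene cig2 fell by 0.97, and of 16 MBF genes 2 were lower and 1 higher, also adjusted over the list alone, or 7 and 2 with the block (camera adjusted p = 0.0546). Of 19 core stress genes 5 were lower and 2 higher, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0958).

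Among genes that act in silencing, 6 of 23 for heterochromatin machinery were higher and 1 lower, also adjusted over the list alone, or 16 and 3 with the block (camera adjusted p = 0.15). The RNA-directed RNA polymerase gene rdp1 rose by 0.42 and the helicase gene hrr1 by 0.50, while stc1 fell by 0.45. The H3K9 methyltransferase gene clr4, above background on 1 of 2 wild type arrays, rose by 0.66, but its change was -0.04 with quantile normalization. Of 18 genes for partners of H3K36 methylation 6 were higher and 1 lower, also adjusted over the list alone, or 7 and 2 with the block (camera adjusted p = 0.478). The shugoshin gene sgo2 rose by 0.73 and the Clr6 complex gene cph1 by 0.53. Of 19 wtf elements, all with possibly multi-copy probes and so uncertain, 8 were higher, or 13 with the block, but their median of 0.27 became -0.15 with quantile normalization (camera adjusted p = 0.0223, 0.566 with an estimated correlation and 0.882 with normexp). Of 22 dubious open reading frames 10 were higher and 1 lower, or 14 and 2 with the block, with a median of 0.40 that became -0.11 without the filter (camera adjusted p = 0.0188, 0.349 with an estimated correlation and 0.123 with normexp).

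In housekeeping groups few genes were called. Limma called none of 125 ribosomal protein genes, 74 of them with possibly multi-copy probes, also adjusted over the list alone, and 0 had an unadjusted p under 0.05, against 1 called lower with the block. Their median was -0.02, or 0.01 without replicate 2 of the set2 deletion (camera adjusted p = 0.0267, 0.761 with an estimated correlation and 0.758 with normexp). It called none of 13 chaperone genes, also adjusted over the list alone, against 5 at an unadjusted p under 0.05 and 6 higher with the block (camera adjusted p = 0.193). Of 10 histone genes, 7 with possibly multi-copy probes, 1 was called higher, or 0 adjusted over the list alone and 4 with the block (camera adjusted p = 0.352). Of 11 strain marker genes ura4 alone was called, higher by 0.40, also adjusted over the list alone, or 1 higher and 1 lower with the block (camera adjusted p = 0.694).

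**Figure D2:**
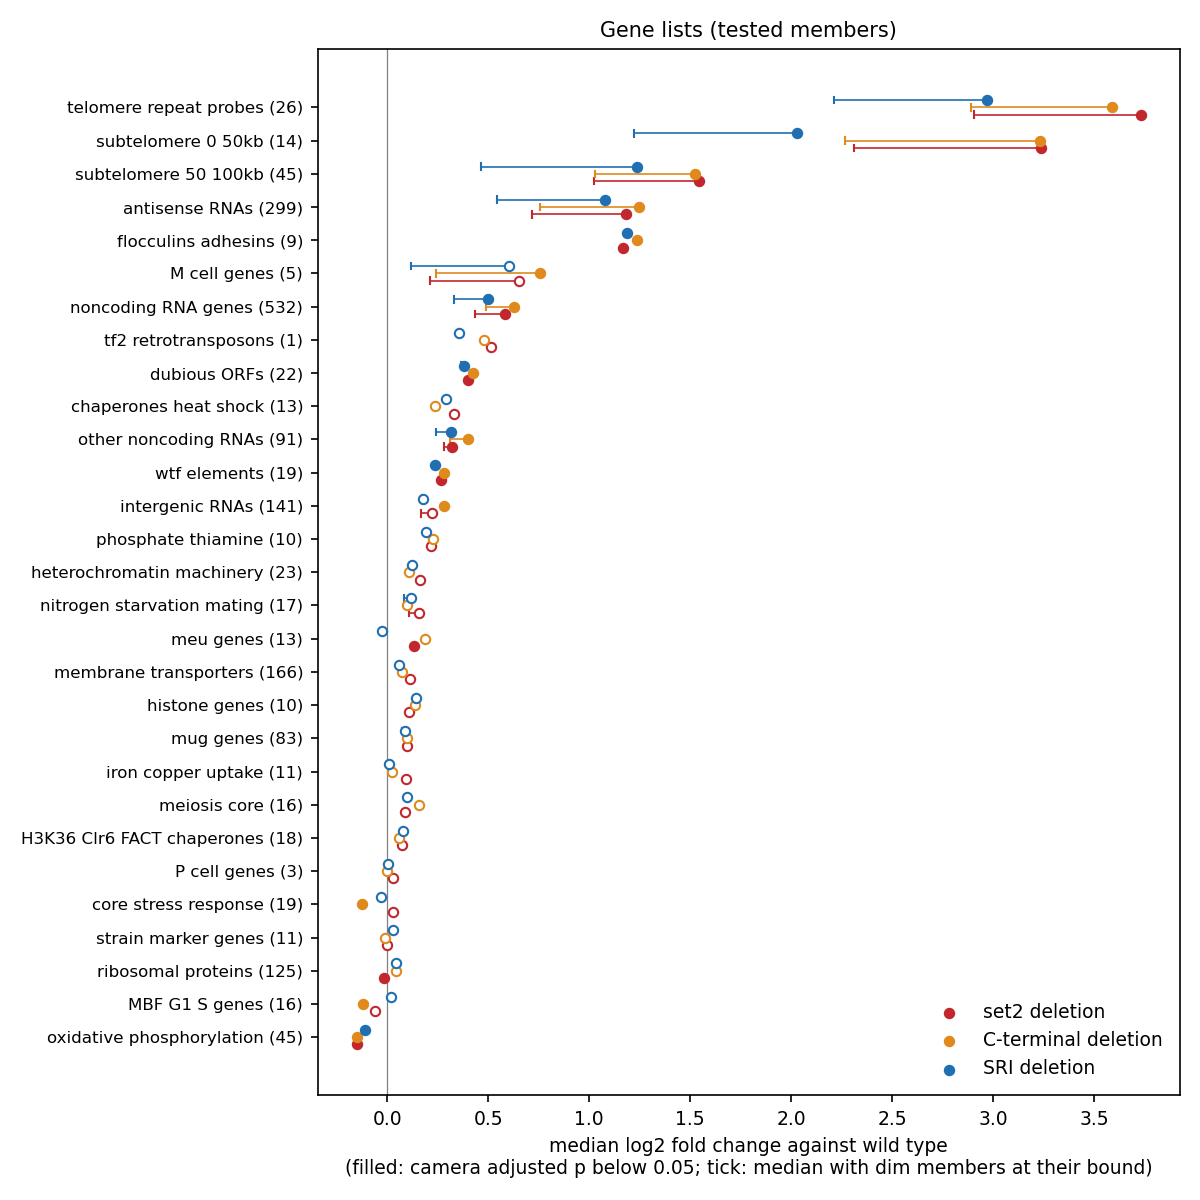
Median log2 change of each gene list (horizontal axis) in the 3 mutants against wild type, with filled points for camera adjusted p under 0.05 and a tick for the median with dim genes at their bound. Medians in the set2 deletion ran from -0.15 for oxidative phosphorylation to 3.73 for telomere repeat probes, and those of meu genes, wtf elements and other noncoding RNAs turned negative with quantile normalization.

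In all, 1510 of 5340 features were called in the set2 deletion, or 2458 with the slide as a block, which kept all 1510. Of those with at least a 2-fold change, 335 were higher and 18 lower. This split was 311 to 22 with median centring, 229 to 50 with quantile normalization and 81 to 4 with normexp. Without the 2-fold limit it depended on the scaling, with 1033 higher and 477 lower (1573 and 885 with the block), or 68.4% higher, against 49.2% with median centring and 40.8% with quantile normalization. All 1510 had the same sign on both slides, and 950 were called without replicate 2 of the set2 deletion.

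**Figure D3:**
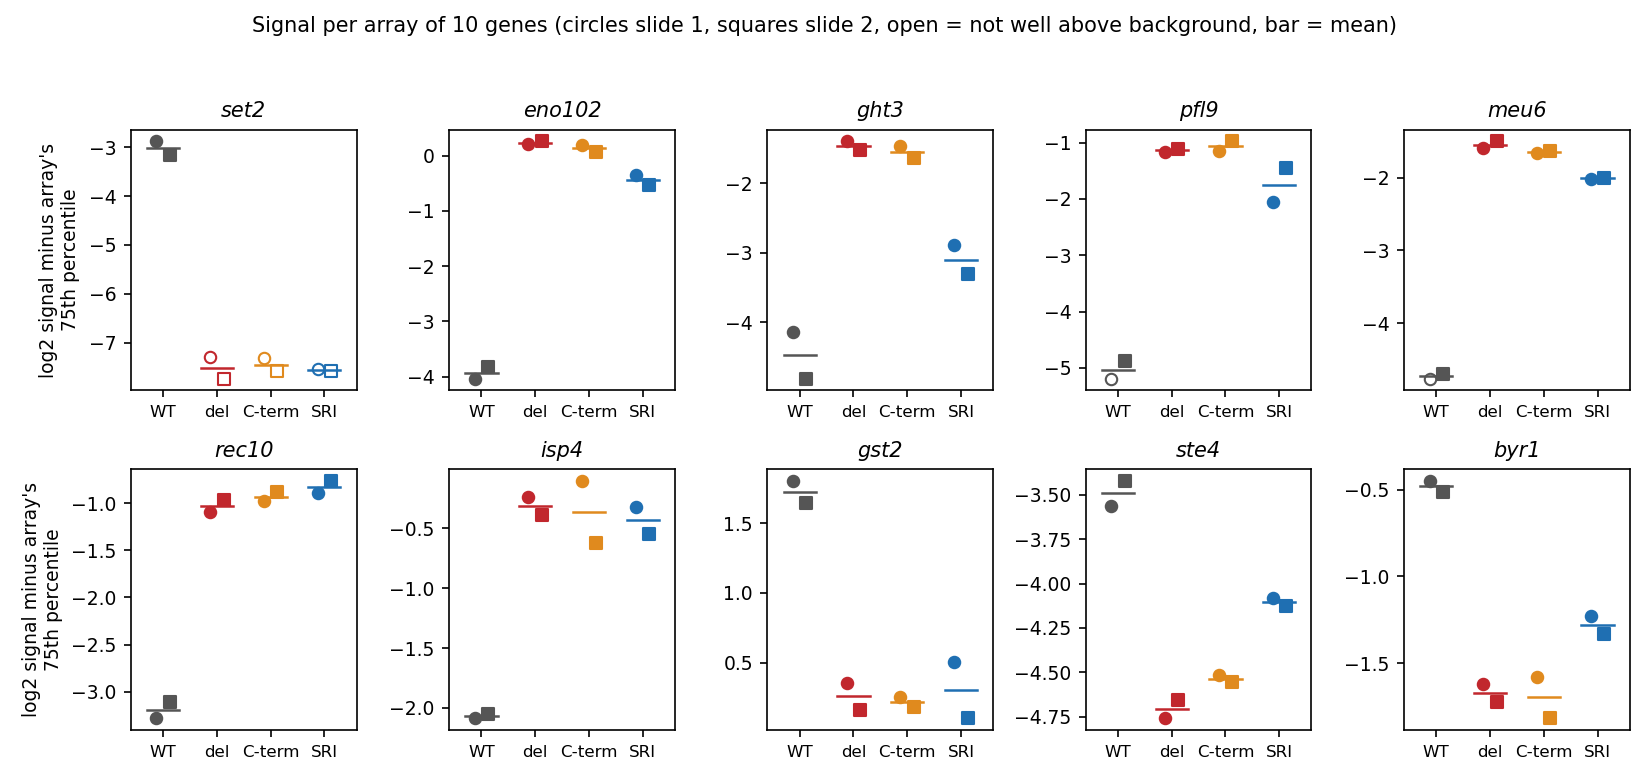
Log2 signal relative to the array's 75th percentile (vertical axis) of 10 genes on each of the 8 arrays by genotype, circles for slide 1 and squares for slide 2, open where the probe was not well above background, with a bar at the mean of 2 arrays. The level of set2 was -3.02 in wild type, and eno102 rose by 4.17 and gst2 fell by 1.46 in the set2 deletion.

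The C-terminal deletion was compared with wild type to ask whether loss of that end of Set2 changes the same RNAs. Here eno102 rose 16.7-fold, by 4.07 ± 0.10, ght3 by 2.93 ± 0.23 and pfl9 by 3.97 ± 0.20. The antisense RNA SPNCRNA.731 rose by 3.42 ± 0.16, and SPNCRNA.554 was at least 12.1-fold higher. The meiotic genes rec10 and meu6 rose by 2.27 and 3.08, while gst2 was 2.83-fold lower and byr1 fell by 1.21. All 14 genes within 50 kb of an end of chromosome I or II were higher, also adjusted over the list alone, with a median of 3.23, or 2.26 with bounds and 1.2 with normexp (camera adjusted p = 4.1e-11, and 0.177 with an estimated correlation). At 50 to 100 kb 35 were higher and 2 lower, or 37 and 2 adjusted over the list alone, with a median of 1.53, or 0.58 with normexp.

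Of 299 antisense RNAs 237 were higher and 8 lower in the C-terminal deletion, with a median of 1.25, or 0.76 with bounds and 0.31 with normexp. Noncoding RNA genes had 333 higher and 24 lower, or 354 and 28 adjusted over the list alone and 382 and 39 with the block, with a median of 0.63, or 0.21 with normexp. All 26 telomere repeat probes were higher, with a median of 3.59, or 2.89 with bounds and 1.47 with normexp (camera adjusted p = 7.7e-20, and 0.0689 with an estimated correlation). Oxidative phosphorylation had 18 lower and 2 higher, or 20 and 4 adjusted over the list alone and 26 and 4 with the block, with a median of -0.15. Flocculins had 7 higher, or 8 adjusted over the list alone (camera adjusted p = 0.00151, and 0.235 with an estimated correlation). The core stress list, with a median of -0.13, and the MBF list, with -0.12, passed camera (adjusted p = 0.0140 and 0.0190) but not with an estimated correlation (0.476 and 0.506). The transcription factor gene ste11 fell by 1.01, mei2 by 0.97 and cig2 by 0.95. In all 1462 features were called, or 2359 with the block, and 346 were at least 2-fold higher against 18 lower. Of the 1462, 1020 were higher and 442 lower (1505 and 854 with the block), or 69.8% higher against 50.2% with median centring and 40.6% with quantile normalization.

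The SRI deletion was compared with wild type to ask whether deleting the polymerase-binding domain changes the same RNAs. Because set2 signal was dim here too, loss of the domain alone was not told apart from a lower level of set2 RNA. Here eno102 rose 11.3-fold, by 3.49 ± 0.10, and ght3 by 1.38 ± 0.23. The flocculin gene pfl9 rose by 3.27 ± 0.20. The antisense RNA SPNCRNA.731 rose by 3.48 ± 0.16, and rec10 and meu6 rose by 2.38 and 2.71. The phosphatase gene SPBPB2B2.06c was at least 29.8-fold higher and SPBPB2B2.08 at least 8.80-fold. Signal for gst2 fell by 1.42, for byr1 by 0.80 and for ste4 by 0.61.

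Within 50 kb of an end of chromosome I or II 13 of 14 genes were higher in the SRI deletion, also adjusted over the list alone, with a median of 2.03, or 1.22 with bounds and 0.58 with normexp (camera adjusted p = 7.5e-10, and 0.202 with an estimated correlation). At 50 to 100 kb 33 were higher and 3 lower, or 35 and 3 adjusted over the list alone, with a median of 1.24, or 0.47 with bounds and 0.42 with normexp. Telomere repeat probes had 25 of 26 higher, with a median of 2.97, or 0.97 with normexp (camera adjusted p = 2.4e-19, and 0.0689 with an estimated correlation). Of 299 antisense RNAs 209 were higher and 8 lower, with a median of 1.08, or 0.54 with bounds and 0.27 with normexp. Noncoding RNA genes had 283 higher and 23 lower, or 322 and 30 adjusted over the list alone and 347 and 43 with the block. Oxidative phosphorylation had 8 lower and 2 higher, also adjusted over the list alone, or 16 and 4 with the block (camera adjusted p = 7.6e-06, and 0.0600 with an estimated correlation). Flocculins had 6 higher, or 7 adjusted over the list alone (camera adjusted p = 0.00153, and 0.235 with an estimated correlation). In all 1139 features were called, or 1998 with the block, and 313 were at least 2-fold higher against 10 lower. Of the 1139, 847 were higher and 292 lower (1342 and 656 with the block), or 74.4% higher against 60.9% with median centring and 45.6% with quantile normalization. Without replicate 1 of the SRI deletion 661 were called, without its replicate 2 707 and without replicate 1 of the wild type 756.

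With an estimated correlation, camera's calls held in all 3 mutants for noncoding RNAs, antisense RNAs and genes 50 to 100 kb from an end, in the full and C-terminal deletions for oxidative phosphorylation, and in the C-terminal and SRI deletions for other noncoding RNAs, although not without the 4 telomere repeat probes in that list (adjusted p = 0.0792 and 0.0892). Of 28 lists tested, 4, 5 and 4 thus passed in the full, C-terminal and SRI deletions, against 12, 14 and 10 at the preset correlation and 22, 22 and 21 with fry. Median and mean had opposite signs for core stress genes in the full deletion (0.0265 and -0.12), meu genes (-0.0258 and 0.69) and MBF genes (0.0203 and -0.0273) in the SRI deletion, and strain marker genes in the full (-0.000501 and 0.0281) and C-terminal (-0.0103 and 0.0187) deletions, none of which passed camera.

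The mutants shared most of their changes. Across the 3 comparisons 782 features were higher in all 3 mutants and 254 lower, out of 1699 called in at least 1, and 0 were called in opposite directions. At least 2-fold higher in all 3 were 299 of 360 that were so in at least 1. Across 5340 features, which are not independent replicates, the log2 changes of the full and C-terminal deletions correlated with Pearson's r of 0.993 and a covariance of 0.452. Simulated unchanged groups that shared a wild type gave 0.497 and 0.00738. The r of the full and SRI deletions was 0.977 (0.499 simulated) and that of the C-terminal and SRI deletions 0.980 (0.500 simulated). Within slides the 3 values of r ranged from 0.965 to 0.989. The slope of the C-terminal on the full deletion was 0.999 and that of the SRI deletion on the full deletion 0.831. Because the same 2 wild type arrays entered every comparison, part of this overlap may come from them. With no array shared, 1 mutant taken on slide 1 and the other on slide 2, each against the wild type array of its slide, r was 0.961 and 0.966 for the full and C-terminal deletions, 0.950 and 0.947 for the full and SRI deletions and 0.949 and 0.937 for the C-terminal and SRI deletions.

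The C-terminal and full deletions were compared with each other to ask whether their effects differ. Between these 2 mutants eno102, with 4.17 and 4.07 against wild type, rec10, with 2.17 and 2.27, and byr1, with -1.19 and -1.21, did not pass the threshold. Limma called 0 features, with the block as well. In the fit without the block 66 had an unadjusted p under 0.05 where 267 would be expected by chance. The spread in that fit holds the shared slide effect, so this low count does not show the effects to be equal. The largest fitted difference was that of the multi-copy probe tlh1, at -2.24, which did not pass. Without replicate 2 of the C-terminal deletion 1 feature was called.

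The SRI deletion was compared with the full deletion to ask whether its effects are smaller. Most of the called genes had lower levels in the SRI deletion. The hexose transporter gene ght3 was 3.12-fold lower, by -1.64 ± 0.23 (SE, 2 arrays against 2), and the siderophore transporter gene str3 (SPAC1F8.03c) by -1.32 ± 0.17, with 1 of the 2 SRI arrays above background. The transporter gene SPBPB8B6.02c differed by -1.37, and the telomere repeat probes Tg15 and Tg16 by -1.83 and -1.55. The antisense RNA SPNCRNA.1451, dim on both SRI deletion arrays, was at least 2.02-fold lower. Of the 3 genes that were higher, ste4 differed by 0.60, SPNCRNA.1482 by 0.60 and SPAC22A12.17c by 0.58. Adjusted p of these named genes lay between 0.0281 and 0.0472.

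As groups, genes within 50 kb of an end of chromosome I or II differed by a median of -0.83 between the SRI and full deletions (camera adjusted p = 9.5e-20, and 0.0784 with an estimated correlation). Those at 50 to 100 kb differed by -0.35 (8.3e-19, and 0.0411) and telomere repeat probes by -0.84 (4.8e-30, and 0.0431). With normexp these 3 medians were -0.50, -0.18 and -0.45. Antisense RNAs differed by -0.12, a median that became 0.03 with normexp (4.4e-12, and 0.0411). The mean differed by -1.48 at 0 to 25 kb, from 2 features with slide values of -0.72 and -2.24, by -0.93 at 25 to 50 kb over 15 features, and by -0.19 at 100 to 125 kb. In all 30 features were called, 3 higher and 27 lower, or 17 and 83 with the block, and 0 with normexp. The count was 0 without either array of the full deletion, 3 without either array of the C-terminal deletion and 2 without replicate 2 of the SRI deletion.

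**Figure D4:**
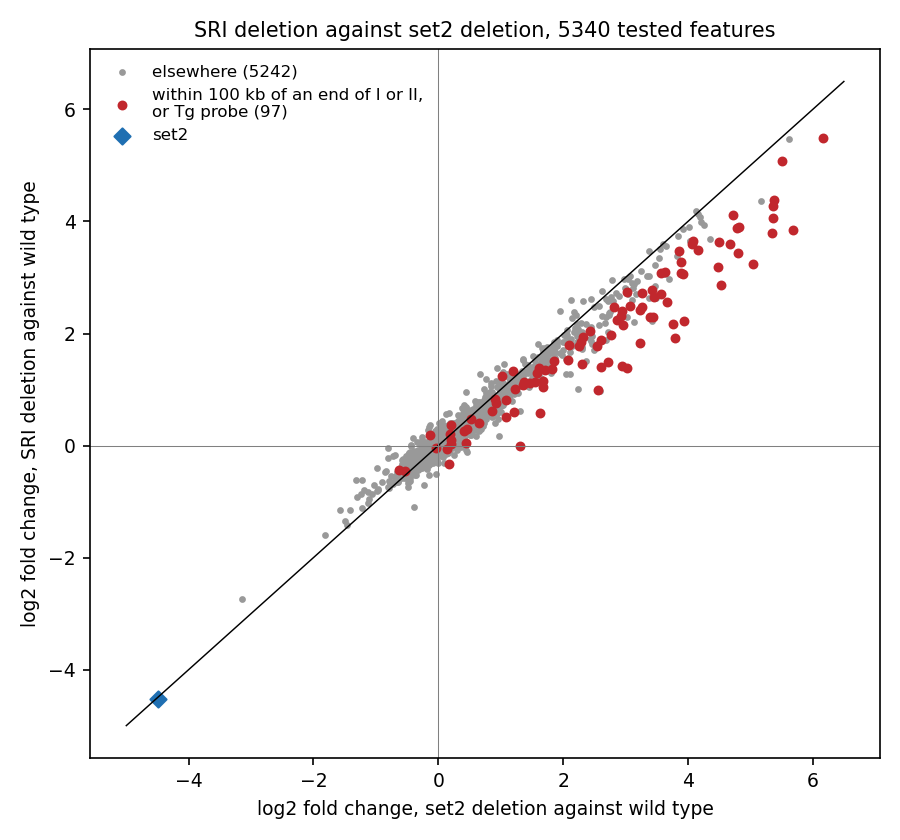
Log2 change against wild type in the SRI deletion (vertical axis) and in the full set2 deletion (horizontal axis) for 5340 features. Red marks those within 100 kb of an end of chromosome I or II and the telomere repeat probes. The slope of genes called higher in the full deletion was 0.757 within 100 kb and 0.888 elsewhere.

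The SRI deletion was compared with the C-terminal deletion for the same question. Here Tg16 differed by -1.67, the noncoding RNA prl61 (SPNCRNA.61, chromosome I, 5546205 to 5546648) by -1.39, SPAC186.03, with a multi-copy probe, by -1.17 and SPAC9G1.14 by -1.09. The alpha-galactosidase gene mel1 and SPNCRNA.1451, dim on both SRI deletion arrays, were at least 1.93-fold and 1.84-fold lower. The dehydrogenase gene SPAC22A12.17c differed by 0.60. Genes within 50 kb of an end of chromosome I or II differed by a median of -0.88 (adjusted p = 0.0784 with an estimated correlation) and those at 50 to 100 kb by -0.34, or -0.52 and -0.22 with normexp. In all 13 features were called, 1 higher and 12 lower, or 8 and 92 with the block, and 0 with normexp. The count was 0 without either array of the full or C-terminal deletion, 2 without replicate 2 of the SRI deletion and 25 without either wild type array.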

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

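The tests of median centring, of multi-copy probes and of the slopes among genes changed at least 2-fold were chosen only after the result was seen. So were the lists of antisense RNAs, intergenic RNAs, other noncoding RNAs, telomere repeat probes, wtf elements, dubious open reading frames and membrane transporters. The SE in this section come from resampling genes and do not measure the spread between cultures.

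More genes rose than fell in the set2 deletion. This excess depended on wild type signal. Open reading frames away from chromosome ends were split by that signal into 4 groups of nearly equal size. From the dimmest group to the brightest, 310, 189, 95 and 30 were higher and 86, 120, 127 and 109 lower. Decreases thus outnumbered rises in the brightest group and the one next to it. In the brightest group this held also in the C-terminal (29 higher, 108 lower) and SRI (22 and 53) deletions. With each array centred on its median, 49.2% of called genes were higher, against 68.4% with the 75th percentile, but such centring itself draws the share towards even, so whether the excess over all called genes comes from the centring stays open. Among genes changed at least 2-fold 93.4% were still higher with median centring. That centring moved the median change of all genes only from 0.0283 to -0.0467, so this share could hardly fall. It shows only that the choice between these centrings is not the source of that part. With quantile normalization the share was 82.1%. Dimmer wild type arrays, which would raise dim features of any class, were tested on 126 antisense RNAs paired with open reading frames within 0.25 of their wild type log2 signal. The antisense median was higher by 0.29 (bootstrap SE 0.07), too near the preset bound of 0.3 to decide. The paired antisense RNAs had a median of 0.45, against 1.18 over all 299, so this tested only part of the rise. On slide 1 wild type was not dimmer than the C-terminal deletion by 75th percentile signal (473 against 470), but was by median (173 against 182). On slide 2 it was not dimmer than the SRI deletion by 75th percentile (669 against 636) or median (245 against 241). Yet in these 2 comparisons 368 and 296 features were at least 2-fold higher and 16 and 13 lower. This argues against dimmer wild type arrays as the source on slide 2, and decides less on slide 1. Fewer probes were well above background in wild type in both comparisons (5034 against 5382 and 5208 against 5374), which either account would give. The full deletion was brighter (512 and 825), so for it this stays open beside an effect of the genotype.

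Genes within 100 kb of the ends of chromosomes I and II rose. The 50 protein-coding genes with probes not marked multi-copy had a median log2 change of 2.42 (SE 0.43) in the set2 deletion, which argues against cross-hybridisation with other copies as the whole source. The 17 genes there with wild type signal above the median of all genes had a median of 0.21 (SE 0.20). Of them 8 were higher and 2 lower, SPBPB8B6.05c at -0.53 and SPAC977.12 at -0.64. A gain of DNA copies over the whole region would raise them too, by at least 0.5. Their median argues against it, but weakly, given its SE and members that moved both ways. Those within 50 kb, gdt1 and gal1, rose by 1.68 and 1.22, so a gain limited to the outermost part stays open for them. Further in, aes1 rose by 1.86 at 70.1 kb, and yhb1 by 1.54 and pan5 by 0.91 at 59.2 kb. The 2 that were lower lay at 54.3 and 56.5 kb. A gain within 50 kb alone would not cover the rises further in. An effect of the genotype stays open and was not tested apart from these explanations, and the pattern was found and weighed on the same data.

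The SRI deletion changed less than the full deletion, and 30 of 5340 genes (limma) differed between them by a test of the difference itself, as did 13 between the SRI and C-terminal deletions. Among genes called higher in the full deletion, the slope of SRI on full deletion changes was 0.757 for the 63 within 100 kb of an end and 0.888 for the 918 elsewhere, a difference of -0.13 (SE 0.02). This SE comes from resampling genes of the same arrays as if they were independent. Camera estimated a correlation of 0.39 between genes within 50 kb, so the SE may be too small. An even weakening of the whole response would give equal slopes, so the difference argues against it as the whole account for these arrays only. On the slide where the difference was nearer 0 it was -0.126, so 1 slide alone was not the source. Restricted to genes changed at least 2-fold, the slopes were 0.757 (54 genes) and 0.894 (248 genes), and those of the C-terminal deletion were 1.00 and 1.02. That the SRI domain may matter more near chromosome ends remains a hypothesis, and compression of fitted changes of dim genes was not excluded. Nor was a lower level of the whole set2 RNA in the SRI deletion excluded.

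Other lists also differed between mutants by camera's test of the difference at the preset correlation. They were not tested without genes near chromosome ends, so some may partly repeat the difference there. An example of such a gene is str3 in the list of iron and copper uptake. Between the SRI and full deletions the median differences were -0.83 and -0.35 for genes within 50 kb and 50 to 100 kb of an end, -0.84 for telomere repeat probes, -0.12 for antisense RNAs, -0.0741 for noncoding RNAs, -0.14 for meu genes, -0.0771 for iron and copper uptake, -0.0382 for membrane transporters, 0.0811 for MBF genes, 0.0629 for ribosomal proteins and 0.0515 for oxidative phosphorylation. Antisense and noncoding RNAs had a median of the other sign with normexp (0.0331 and 0.0643), and that of ribosomal proteins was 0 with quantile normalization. Only the lists at 50 to 100 kb, telomere repeats and antisense RNAs held there with an estimated correlation. Between the SRI and C-terminal deletions they were -0.88, -0.34 and -0.77 for the lists within 50 kb, at 50 to 100 kb and of telomere repeats, -0.15 for antisense RNAs, -0.13 for noncoding RNAs, -0.0824 for intergenic RNAs, -0.0771 for other noncoding RNAs, -0.12 for M-cell genes, -0.17 for meu genes, -0.0779 for iron and copper uptake, -0.0657 for wtf elements, 0.0985 for core stress genes, 0.11 for MBF genes and 0.0563 for oxidative phosphorylation. With quantile normalization the medians of intergenic and other noncoding RNAs were 0.00333 and 0.00183, and that of iron and copper uptake was also positive with 1 array left out, up to 0.0188. The lists at 50 to 100 kb, telomere repeats, antisense RNAs, noncoding RNAs and other noncoding RNAs held with an estimated correlation, the last not without its 4 telomere repeat probes (median -0.0562, adjusted p = 0.0851).

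Of the 104 probes with the unexplained prefix ho-, which were outside the gene tests, 2 were called in every mutant. Both carry the name of SPBPB21E7.09, a gene near an end of chromosome II. Probe a rose by 2.09 in the full deletion, 2.02 in the C-terminal deletion and 1.28 in the SRI deletion, and probe b by 1.89, 1.85 and 1.12, while the gene's own probe rose by 1.67, 1.63 and 1.05.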

How the results depend on the processing

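Leaving out multi-copy probes and comparing the mutants with no array shared were chosen only after the data were seen. So were the bounds in the means by distance, leaving telomere repeat probes out of other lists and the 7 lists from the array annotation. Every gene had 1 probe in the gene tests, so taking the brightest probe changed nothing and tests nothing. In the sentences below the order is full, C-terminal and SRI deletion, each against wild type, unless pairs are named, and the cause of a change was not tested unless it is given.

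The counts of called genes were 545, 546 and 343 with normexp, whose offset shrinks changes of dim genes, 2458, 2359 and 1998 with the slide as a block, 353, 364 and 323 with at least a 2-fold change, and 913, 880 and 655 at adjusted p under 0.01. Under the other alternatives they stayed within 1.5 times the reported counts, apart from arrays left out. A like count need not mean the same genes. Quantile normalization called 1658, 1667 and 1216, of which 1135, 1108 and 841 were among the reported 1510, 1462 and 1139. With median centring 1308, 1269 and 1014 of the reported genes were called. Leaving out 1 array, which assumes that a lone array varies like the other genotypes, gave 950 to 1548 genes for the full deletion and 661 to 1171 for the SRI deletion. The fewest came without replicate 2 of the full deletion and without replicate 1 of the SRI deletion.

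Of the comparisons between mutants, the SRI against the full deletion (30 genes) gave 0 with normexp, 1 without the filter, 1 with only genes well above background on all arrays, 100 with the block, 15 with a trended robust prior, 15 without multi-copy probes, 11 with at least a 2-fold change, 0 at adjusted p under 0.01, and 0 to 33 with 1 array left out. The SRI against the C-terminal deletion (13 genes) gave 0 with normexp, 0 without the filter, 1 with the strict filter, 100 with the block, 2 with only the arrays of these 2 genotypes, 27 with the value table, 0 without multi-copy probes, 7 with at least a 2-fold change, 0 at adjusted p under 0.01, and 0 to 25 with 1 array left out. The C-terminal against the full deletion gave 0 to 1 with 1 array left out, the 1 without replicate 2 of the C-terminal deletion.

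Of 5452 values of called named genes over all alternatives, 5127 kept their direction and call, 315 kept their direction only and 10 changed sign. Normexp ended 123 of 298 such calls and quantile normalization 27. The total holds 298 values of the brightest probe, which could not differ. With the block, the trended robust prior or only the arrays compared, the call could change but not the direction. The sign changed for mam2 (-0.20 with quantile normalization and -0.0293 with normexp, full deletion; -0.0577, C-terminal, and -0.0893, SRI, with quantile normalization), fbp1 (-0.33 and -0.0522, full; -0.35, C-terminal, and -0.24, SRI, with quantile normalization), clr4 (-0.0369) and rad3 (-0.0197, both full deletion with quantile normalization). The genes mam2 and fbp1 were dim on both wild type arrays.

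The block changed the camera call of meu genes and of M-cell genes in the full deletion (adjusted p = 0.0677 and 0.0462) and of no other list. Without the block, M-cell genes there had a camera adjusted p of 0.439 with an estimated correlation. With an estimated correlation 3, 3 and 2 of the fixed lists passed. Genes within 50 kb of an end kept their medians of 3.23, 3.23 and 2.03 but not their call (adjusted p = 0.177, 0.177 and 0.202). Of 747 medians of called lists, 665 kept direction and call, 69 kept direction only and 13 changed sign. With quantile normalization the medians of other noncoding RNAs were -0.10 (full) and -0.0276 (C-terminal), of wtf elements -0.15, -0.16 and -0.18, of meu genes -0.0332 (full) and of intergenic RNAs -0.27 (C-terminal). Without the filter those of other noncoding RNAs were -0.14, -0.0452 and -0.13, and of dubious open reading frames -0.11 (full) and -0.0469 (SRI), where more dim probes enter. Ribosomal proteins in the full deletion ranged from -0.0560 to 0.0147 with 1 array left out. With only genes above background on all arrays the medians were 0.46, 0.50 and 0.36 for antisense RNAs, 0.28, 0.33 and 0.24 for noncoding RNAs and 0.59, 0.61 and 0.43 for genes at 50 to 100 kb, and with quantile normalization those of antisense RNAs were 0.60, 0.64 and 0.51. In the SRI deletion 5 to 8 lists passed with 1 array left out.

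For genes and lists that did not pass, no rise or fall is stated, and a sign printed for some of them is not a call. After the table had been seen, it was limited to the p-values of those lists and to called genes, since the sign of an uncalled value carries little: 24 of 1166 values of uncalled named genes and 90 of 1008 of uncalled lists had the other sign under some alternative.

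Pearson's r between the full and C-terminal deletions was 0.973 with normexp, 0.982 with only genes above background on all arrays, 0.996 over called genes, and 0.982 to 0.993 with 1 array left out. Between the full and SRI deletions it was 0.945, 0.955 and 0.964 to 0.978 for normexp, the strict filter and 1 array left out, and between the C-terminal and SRI deletions 0.961, 0.965 and 0.967 to 0.981.

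The mean within 100 kb of an end minus that beyond 200 kb was 1.88, 1.87 and 1.32 with quantile normalization, 0.87, 0.87 and 0.58 with normexp, 1.44, 1.45 and 0.98 without the filter, 1.15, 1.13 and 0.82 with only genes above background on all arrays, and 2.14, 2.13 and 1.57 without multi-copy probes. With 1 array left out it was 2.01 to 2.06, 1.99 to 2.06 and 1.42 to 1.53. Signal over background is the limit here, since many genes near the ends are dim in wild type and their fitted changes depend on the background correction.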

Other observations

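The tests on the genes beside set2 were chosen only after the result was seen.

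A first hypothesis was that a risen antisense RNA lowers the gene it overlaps. In the set2 deletion the median log2 change of the 211 open reading frames under a risen antisense RNA was 0.07, with 55 higher and 25 lower, and that of the 50 under another antisense RNA was 0.03, with 10 higher and 4 lower. The difference of 0.0385 (two-sided permutation test, p = 0.514) was not in the direction this hypothesis needs, and Spearman's rho across 263 pairs was 0.00463. No lowering of the overlapped genes was thus detected in this test. The files do not state the strand that the probes of open reading frames read, and it was not derived from the probe sequences. Whether these values are of the sense RNA was therefore not determined.

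A second hypothesis was that long genes rise more. Away from chromosome ends, length and change in the set2 deletion had a Spearman's rho of 0.162 across 4561 open reading frames, which are not independent replicates. Within 3 equal groups by wild type signal rho was 0.241 in the dimmest, 0.201 in the middle and 0.0785 in the brightest, which lies under the bound of 0.1 set in advance for all 3. Of the longest 1139 genes, with a median length of 2613 bases, 236 were higher and 51 lower, and of the shortest 1139 111 were higher and 151 lower. A relation of length and change may thus hold among dim and middling genes and was not shown for bright ones.

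A further hypothesis was that the altered locus itself changes its neighbours. Of 8 genes within 10 kb of set2, 6 were called in the full deletion, against 23.6% of the other tested genes annotated as protein-coding (two-sided Fisher's exact test, p = 0.00315), while 2 were called in the C-terminal deletion and 1 in the SRI deletion (p = 1 in both). By their coordinates the 8 genes lie roughly 150 to 200 kb from an end of chromosome I. On chromosomes I and II 18 of 49 features at 150 to 175 kb were higher in the full deletion and 3 lower. At 175 to 200 kb 11 of 47 were higher and 3 lower. These counts include the neighbours, and Fisher's test was not matched for distance. In the full deletion chl1 rose by 0.52, snz1 by 0.53, spd1 by 0.50 and ino80 by 0.31, and chl1 rose also in the C-terminal and SRI deletions, by 0.44 and 0.35. Between the C-terminal and full deletions none of the 8 passed when adjusted over all features (adjusted p = 0.999 for each), but snz1 (-0.30), spd1 (-0.35) and ino80 (-0.16) passed when adjusted over the 8 alone (adjusted p = 0.0314, 0.0347 and 0.0347). Between the SRI and full deletions the adjusted p over all features was at least 0.135, and these 3 and rcd1 (-0.23) passed over the 8 alone (adjusted p = 0.0144, 0.0294, 0.0277 and 0.0288). With the slide as a block all of these passed over the 8 alone. So did rcd1 between the C-terminal and full deletions (limma adjusted p = 0.0452) and chl1 between the SRI and full deletions (0.0200). The neighbours were chosen for testing after their values on the full deletion arrays had been seen. The same arrays are the reference in these differences between mutants, which favours negative values. Passing over the 8 alone therefore adds no support for an effect of the locus. An effect of the altered locus on nearby genes may account for the values in the full deletion. It was not told apart from distance to the chromosome end, and 8 neighbours are few.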
